A study of Homo sapiens with 16 samples.

How the data were processed

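Total RNA was sequenced from 16 libraries of MCF7, an established estrogen receptor positive breast cancer cell line. Per the labels, the cells carried lentiviral constructs selected with puromycin, and strand-specific mRNA libraries were read as paired ends on a DNBSEQ instrument. The 8 groups held 2 libraries each and fell into 3 experiments. The AGPG knockdown set shAGPG1 and shAGPG2 against shCon, the AGPG overexpression set plvx_AGPG against the vector plvx, and the PURA knockdown set shPURA1 and shPURA2 against shCon_PURA. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values of single genes measure only the spread between samples. Those of the gene lists from camera, described below, also rest on the spread among genes and on a preset or estimated correlation.

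The deposited files gave raw counts per gene, 1 library per file. The submitters' processing notes name HISAT2, SAMtools, featureCounts and DESeq2 with genome build GRCh38. The annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here. Of 60660 gene identifiers, 60419 matched a name table, and gene positions were taken from GENCODE release 29 on GRCh38. The cell for ANK2 was blank in 6 libraries, all of the PURA experiment, so that gene was treated as missing there. Library totals ran from 15339258 to 19683199 counts. AGPG was matched to the gene symbol ACTG1P25, an actin gamma 1 pseudogene, through the name table.

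Each experiment was fitted alone, so that its groups shared an estimate of the spread and no batch was assumed. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15) and scaled by TMM. They were then tested with the robust quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. The threshold was an adjusted p of 0.05. A gene was taken as changed in a knockdown when both hairpins passed with the same sign. Differences between hairpins against a fold of 2 used glmTreat. CPM values are TMM-scaled counts and are given with the SD over the 2 libraries of a group. Errors of log2 fold changes are standard errors.

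Of 20 gene lists, each was tested with camera (limma 3.58.1, preset correlation 0.01) and adjusted over the lists of a comparison, and camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera takes its degrees of freedom from the libraries rather than from the genes. Its p-values can therefore rise without a higher correlation, and they are not on the same scale between fits of different size. The lists, the comparisons, the tests, the rule for named genes and most alternatives were written before the data were examined. Under that rule 12 genes were named in every comparison. To these came the 8 genes that rose and the 8 that fell most in each experiment, with a symbol, passing in every treated group, with all treated libraries beyond both control libraries and a mean of at least 5 CPM. For each list, up to 4 of its changed members with the largest change were added, or the 2 most abundant where none changed. In addition, 2 panels (the E2F and RB family, and endocrine response and resistance) were described gene by gene without a set test. Gene-by-gene values are given for a selection of the named genes.

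A fold against a group with no counts was computed against a floor of 3 counts over the group and is given as a lower bound. Where a group held 1 to 3 counts, the ratio is given with its 95% counting interval. Such intervals and floors cover counting error only. The medians of the 60 list results did not move when genes with no counts in a group were set to their bounds. For the 2 knockdowns, whose hairpins share their controls, 25 simulated data sets with no effect gave the overlap and the covariance that sampling noise in shared controls produces. All groups were drawn from 1 common mean per gene, so a control that stands apart was not simulated. Regional effects were looked for in windows of 50 consecutive tested genes, whose median was compared with the median of all genes and with 100 permutations of gene positions.

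The pipeline was tested on simulated data with 200 genes and 1 list changed among counts drawn with 1 common mean per gene and the fitted dispersions. In the data themselves far more genes changed: 70.4% in both AGPG hairpins, 65.7% in the overexpression and 36.4% in both PURA hairpins. The recovery and false calls below therefore speak only for data in which most genes are unchanged. In the AGPG knockdown design, with 14804 genes tested, 52.2% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 89.4% of those changed 4-fold were recovered in both hairpins, and 3 unchanged genes were called. For the overexpression design, with 14463 genes tested, these shares were 47.8%, 65.7% and 97.0%, with 12 unchanged genes called. For the PURA design, with 15690 genes tested, they were 53.7%, 64.2% and 97.0%, with 0 unchanged genes called. A raised hypoxia list was called by camera in all 3 designs with 0 of the 19 other lists. All 12 of 12 planted windows were found. Their shift was added directly to the log2 fold changes and exceeded the threshold of 0.5. That outcome was all but fixed in advance and checks the code only. Replicate libraries differed more than counting error alone allows, with a chi-square per degree of freedom from 3.78 to 12.5.

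Alternatives were DESeq2 1.42.0 in place of edgeR, its size factors, library totals without TMM, no low-count filter, a minimum mean of 1 or 10 CPM, a log2 fold change of at least 1, all 16 libraries in 1 fit, the replicate number as a block, each hairpin alone, and leaving out each library in turn. After the data were seen, 3 alternatives were added: leaving out mitochondrially encoded genes, taking control libraries of another experiment, and a crossed pairing of replicate numbers in the overexpression. With library totals alone, the median log2 fold change of all genes moved from 0.008 to -0.228 in the AGPG knockdown and from 0.002 to 0.209 in the overexpression, so changes are reported relative to TMM scaling. No tested gene was left out by hand.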

Results

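The data were gene counts from 16 MCF7 libraries in 8 groups of 2. Library totals were 15339258 to 17506056 counts in the 5 groups of the AGPG experiments and 19236141 to 19683199 in the 3 groups of the PURA experiment. Mitochondrially encoded genes took 8.87% ± 0.197 of the counts in shCon and 8.54% ± 0.303 in plvx_AGPG (SD, n = 2). They took 16.6% ± 1.55 in shAGPG1, 18.4% ± 0.467 in shAGPG2 and 17.6% ± 1.72 in plvx. In the PURA experiment the share was 13.9% ± 1.61 in shCon_PURA, 12.6% ± 0.318 in shPURA1 and 15.2% ± 1.46 in shPURA2. The first principal component of all libraries held 62.7% of the variance and set shAGPG1, shAGPG2 and plvx apart from the other 5 groups. The second held 20.6% and set shCon_PURA, shPURA1 and shPURA2 apart from shCon and plvx_AGPG.

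**Figure D1:**
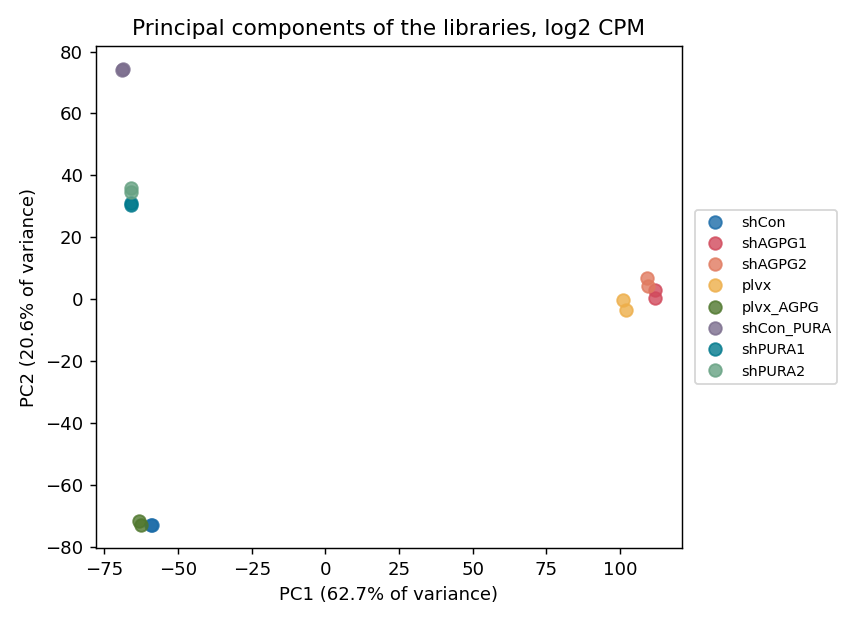
Principal component scores of the 16 libraries from log2 CPM, each point a library, colored by group, with the percent of variance on each axis. The shAGPG1, shAGPG2 and plvx libraries lie together at the right, and shCon lies beside plvx_AGPG.

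The long noncoding RNA AGPG, named in the series title together with E2F1 activity and endocrine resistance, was measured first as the target of the knockdown and the overexpression. It is annotated as ACTG1P25 (ENSG00000234996.4), a transcribed processed pseudogene on chromosome 1, 202861754 to 202875241, plus strand, GRCh38. One of its annotated transcripts has 3 exons, and its reads may overlap those of ACTG1 and other actin copies. AGPG was at 2.05 ± 0.28 CPM in shCon, 0.437 ± 0.26 in shAGPG1 and 0.748 ± 0.16 in shAGPG2 (SD, n = 2). It fell by 2.20 on the log2 scale in shAGPG1 (SE 0.42, edgeR adjusted p = 1.5e-05) and by 1.44 in shAGPG2 (SE 0.38, adjusted p = 0.00089). The counts behind these values were 32 and 40 in shCon, 4 and 10 in shAGPG1, and 10 and 14 in shAGPG2. In the overexpression AGPG rose 56.0-fold, from 0.636 ± 0.02 CPM in plvx to 36.0 ± 2.6 in plvx_AGPG (log2 5.81, SE 0.21, edgeR adjusted p = 2.4e-11, n = 2). The plvx libraries, which carry no hairpin against AGPG, held 10 and 10 counts. In a fit of all 16 libraries AGPG was 3.27-fold lower in plvx than in shCon (log2 -1.71, SE 0.32, edgeR adjusted p = 3e-05). Against plvx, AGPG did not differ in shAGPG1 (log2 -0.50, SE 0.45, adjusted p = 0.51) or shAGPG2 (log2 0.25, SE 0.40, adjusted p = 0.73).

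PURA, which encodes a nucleic acid binding protein (chromosome 5, 140107777 to 140125619, GRCh38), was the target of the other knockdown. It was at 21.9 ± 0.37 CPM in shCon_PURA, 15.5 ± 0.67 in shPURA1 and 19.8 ± 0.21 in shPURA2 (SD, n = 2). PURA fell 1.41-fold in shPURA1 (log2 -0.50, SE 0.10, edgeR adjusted p = 0.00037). The difference in shPURA2 was 1.11-fold and did not pass (log2 -0.15, SE 0.10, adjusted p = 0.23). In the fit of all 16 libraries PURA was already 2.24-fold lower in shCon_PURA than in shCon (log2 -1.16, SE 0.10, edgeR adjusted p = 1e-11), and against shCon it passed in shPURA2 as well (log2 -1.31, adjusted p = 1.9e-12). AGPG did not change in shPURA1 (log2 -0.22, SE 0.20, adjusted p = 0.38) or shPURA2 (log2 -0.36, SE 0.20, adjusted p = 0.17).

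**Figure D2:**
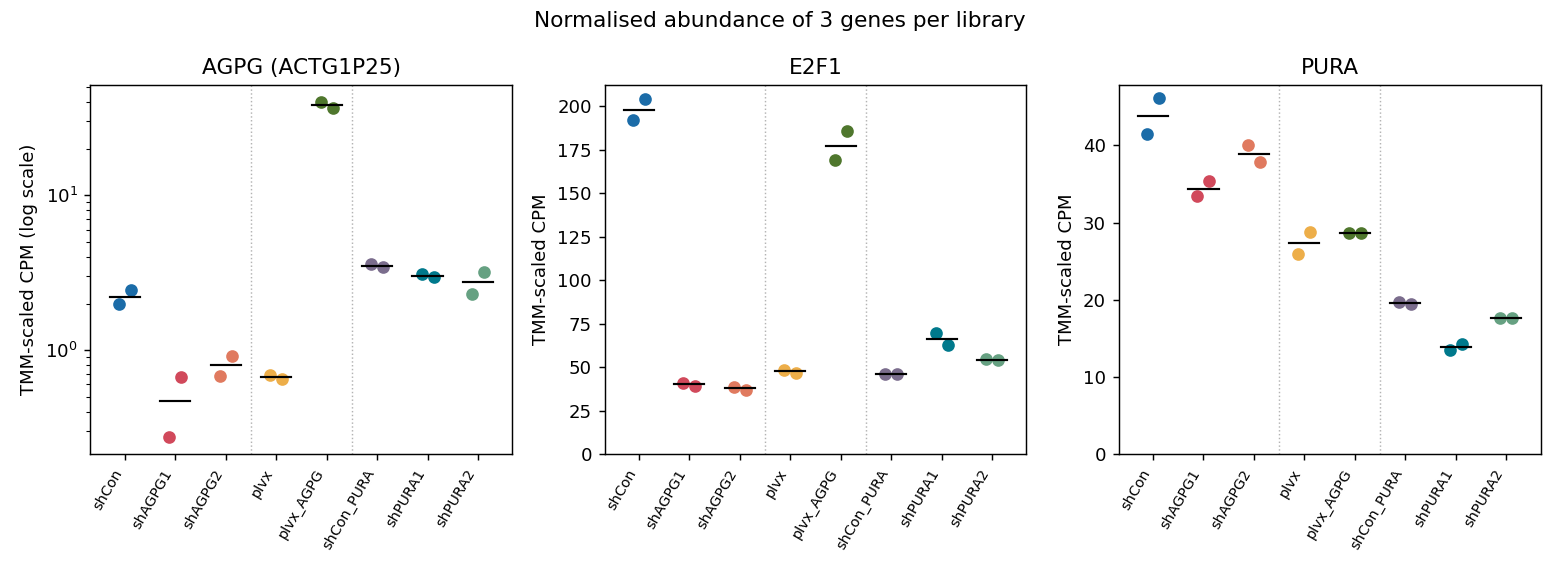
TMM-scaled CPM of AGPG (log scale), E2F1 and PURA in each library, from 1 scaling over all 16, with points for libraries and lines for group means. AGPG averaged 2.21 CPM in shCon, 0.672 in plvx and 38.4 in plvx_AGPG.

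Knockdown of AGPG asks which transcripts depend on it. In both hairpins 10767 of 15290 genes changed in the same direction, 5465 up and 5302 down, and 5168 of them at least 2-fold in each. By hairpin, 11508 genes changed in shAGPG1 (5799 up, 5709 down) and 11478 in shAGPG2 (5879 up, 5599 down). None of the 8 genes that ranked highest among those that rose, by fitted fold, had a count in shCon. The calcium channel subunit CACNG4 (chromosome 17, 66964910 to 67033398) was at 179 ± 2.0 CPM in shAGPG1 and 185 ± 5.4 in shAGPG2 (SD, n = 2), at least 2090-fold and 2160-fold higher. The lysosomal enzyme gene GALC was at least 625-fold and 619-fold higher and the amino acid transporter SLC6A14 at least 480-fold and 504-fold. The ligand gene SHH was at least 301-fold and 337-fold higher, with KLK11, ARMCX1, ROBO1 and BPIFB1 each at least 211-fold higher in both hairpins. Among the genes that fell most, INSYN1 went from 269 ± 19 CPM to 1.00 ± 0.074 and 1.03 ± 0.15 (log2 -8.05 and -8.02, SE 0.13, adjusted p = 1e-35 in each). Its antisense neighbour INSYN1-AS1 was at least 216-fold and 217-fold lower, and TRIP6 fell 113-fold and 102-fold from 506 ± 5.0 CPM. RAB34, TRPM2, GUCY1A2, CBLC and VAV1 completed the 8 that fell most. The plvx libraries, which carry no hairpin, resembled the shAGPG libraries in those of these genes also named in the overexpression. They held 9780 counts of CACNG4, 2763 of SLC6A14, 2095 of GALC, 970 of SHH and 951 of BPIFB1. Of genes that fell, they held 3 counts of RAB34, 2 of CBLC and 1 each of INSYN1-AS1 and GUCY1A2.

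E2F targets and DNA replication genes fell after AGPG knockdown. Their median log2 fold change over 70 genes was -1.13 in the mean of both hairpins, and 69 fell, also 69 when adjusted over the list alone (camera adjusted p = 9.9e-20, and 0.023 with an estimated correlation). Both hairpins passed for 67 of the 70. E2F1 itself went from 183 ± 8.2 CPM in shCon to 37.5 ± 1.2 in shAGPG1 and 35.4 ± 1.4 in shAGPG2 (log2 -2.29 and -2.37, SE 0.07 each, edgeR adjusted p = 6.4e-26 and 2.7e-26). The helicase subunit MCM7 fell 4.04-fold and 4.25-fold, CDCA7 3.85-fold and 3.77-fold, and the polymerase subunit POLA1 3.79-fold and 3.71-fold. The mitosis list fell with a median log2 fold change of -1.03 over 64 genes, 58 of which fell and 1 rose, with 59 changed when adjusted over the list alone (camera adjusted p = 2.6e-13, and 0.047 with an estimated correlation). PBK fell 5.03-fold and 4.88-fold, GTSE1 3.68-fold and 3.92-fold. Of the 13 members of the E2F and RB family panel, 8 fell and 3 rose in both hairpins. The fall of E2F8 (log2 -0.35 and -0.36) was lost without shCon replicate 1 (adjusted p = 0.15 and 0.13), in shAGPG1 with DESeq2 (0.063) or without shAGPG1 replicate 1 (0.098), and in shAGPG2 without shAGPG2 replicate 2 (0.26). E2F2 fell 3.48-fold and 3.36-fold, TFDP1 1.93-fold and 1.87-fold, and RBL1 by log2 1.32 and 1.31, while the repressive pocket protein genes RB1 (1.57-fold and 1.72-fold) and RBL2 (1.70-fold and 1.74-fold) rose. Against plvx in the fit of all 16 libraries, the E2F list was lower in the shAGPG libraries (median log2 -0.47, 61 of 70 fell, camera adjusted p = 1.4e-21, and 0.00029 with an estimated correlation), as was the mitosis list (median -0.62, 62 of 65 fell, camera adjusted p = 5.7e-41, and 8.2e-05 with an estimated correlation). AGPG itself did not differ in that comparison (log2 -0.12, SE 0.37, edgeR adjusted p = 0.86), so these differences came without a detected difference in AGPG. E2F2 (log2 -0.52), RBL1 (-0.47) and RBL2 (0.67) kept their direction and passed there, while TFDP1 (-0.05, edgeR adjusted p = 0.59) and RB1 (0.04, adjusted p = 0.80) did not differ from plvx.

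Genes of the endocrine panel, which was described without a set test, changed with AGPG knockdown as well. The progesterone receptor gene PGR rose 62.3-fold and 61.5-fold, from 0.914 ± 0.26 CPM to 57.3 ± 1.3 and 56.6 ± 0.099 (log2 5.96 and 5.94, SE 0.15, edgeR adjusted p = 1.3e-29 and 1.5e-29). ESR1, which encodes the estrogen receptor, rose 1.31-fold and 1.33-fold from 147 ± 4.7 CPM. The inhibitor CDKN1A rose 6.10-fold and 5.85-fold, CDK6 19.1-fold and 19.9-fold, IGF1R 3.29-fold and 3.55-fold and CCND1 1.45-fold and 1.46-fold. BCL2 fell 9.27-fold and 9.04-fold, CCNE1 2.31-fold and 2.36-fold, CCNE2 1.65-fold and 1.53-fold and MYC 1.77-fold and 1.63-fold. PFKFB3, a glycolytic regulator, rose 1.63-fold and 1.54-fold, and ACTG1, the parent of the pseudogene, 3.04-fold and 3.12-fold. With plvx in place of shCon, CDK6 (log2 0.08 and 0.12) and PFKFB3 (0.02 and -0.06) no longer passed, and ACTG1 (-0.52 and -0.49) and CCND1 (-0.28 and -0.28) reversed. CCNE2 was lost in shAGPG2 (-0.36, adjusted p = 0.064). In the mean of both hairpins against plvx, BCL2 turned to 0.26 (adjusted p = 0.097), and IGF1R (0.10, adjusted p = 0.33) and CCNE1 (-0.19, adjusted p = 0.23) did not pass. PURA fell in shAGPG1 (log2 -0.34, SE 0.09, adjusted p = 0.00064) but did not pass in shAGPG2 (log2 -0.16, SE 0.09, adjusted p = 0.091), where it passed without shCon replicate 1 (adjusted p = 0.038), and it was higher against plvx in both (log2 0.33 and 0.51). PGR and CDKN1A also differed in the same direction between the controls, higher in plvx than in shCon by log2 3.64 and 1.53 in the fit of all 16 libraries. All 20 genes of the endocrine panel changed in both hairpins, 11 up and 9 down, though the rise of NF1 in shAGPG1 (log2 0.21, SE 0.08, edgeR adjusted p = 0.026) turned to -0.04 when scaled by library totals. It was also lost with DESeq2 (adjusted p = 0.072), in the fit of all 16 libraries (0.18) and without shCon replicate 2 (0.19) or shAGPG1 replicate 2 (0.46). In shAGPG2 the rise of NF1 (log2 0.28, adjusted p = 0.0030) was lost with library totals (0.05, adjusted p = 0.60) and in the fit of all 16 libraries (0.078).

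Among the other lists, estrogen response genes rose after AGPG knockdown with a median log2 fold change of 0.79 (30 of 47 rose and 15 fell; 45 changed when adjusted over the list alone; camera adjusted p = 0.00066, and 0.095 with an estimated correlation). Of its members, AREG rose 64.8-fold and 63.2-fold and ELOVL2 359-fold and 387-fold, and KRT13, with 1 count in shCon, stood at ratios of 1050 (counting interval 187 to 41300) and 988 (177 to 39100). Luminal identity genes rose (median 0.45, 21 of 25, 23 changed when adjusted over the list alone, camera adjusted p = 2.2e-05, and 0.14 with an estimated correlation), led among abundant members by TFF3 at 25.6-fold and 23.4-fold and XBP1 at 3.26-fold and 3.13-fold. Basal and mesenchymal genes rose too (median 1.85, 11 of 15, 14 changed when adjusted over the list alone, camera adjusted p = 0.00073, and 0.15 with an estimated correlation), with FN1 at 19.5-fold and 19.6-fold, and CD44, without a count in shCon, at least 127-fold and 139-fold higher. Targets of p53 rose (median 0.86, 24 of 30, 28 changed when adjusted over the list alone, camera adjusted p = 1.3e-06, and 0.068 with an estimated correlation), including GDF15 at 11.4-fold and 11.2-fold. Replication-dependent histone genes had a median of 2.19 (32 of 36 rose, 33 changed when adjusted over the list alone, camera adjusted p = 1e-05, and 0.095 with an estimated correlation), with H2BC8 at 11.5-fold and 13.7-fold. Some members of this list held few counts. H3C3 had 0 in shCon against 21 and 29 in the hairpin groups, and H2AC17 had 2 against 26 and 22. Actin and SRF target genes rose (median 0.48, 17 of 25, 22 changed when adjusted over the list alone, camera adjusted p = 0.001, and 0.11 with an estimated correlation), FOS by 8.71-fold and 8.52-fold. These lists stood higher in plvx than in shCon as well, with medians of 0.51 (estrogen), 0.66 (luminal), 2.72 (basal), 0.45 (p53), 1.86 (histones) and 0.86 (actin) in the fit of all 16 libraries. Set against plvx, the shAGPG libraries no longer passed for estrogen response (median 0.08, camera adjusted p = 0.097), luminal identity (0.08, 0.18) or histones (-0.04, 0.15), and basal (-0.55, 0.0038) and actin genes (-0.42, 1.1e-10) were lower. Targets of p53 stayed higher (0.27, 1.2e-05, and 0.0040 with an estimated correlation), though AGPG itself did not differ in that comparison.

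MYC targets and ribosome biogenesis genes fell after AGPG knockdown (median log2 -0.81, 24 of 28, 26 changed when adjusted over the list alone, camera adjusted p = 1.4e-07, and 0.31 with an estimated correlation), TCOF1 by log2 2.33 and 2.26. Ribosomal protein genes rose (median 0.71, 49 of 64, 56 changed when adjusted over the list alone, camera adjusted p = 4.4e-08, and 0.50 with an estimated correlation). Mitochondrially encoded genes rose (median 1.03, 12 of 13, 13 changed when adjusted over the list alone, camera adjusted p = 2e-04, and 0.50 with an estimated correlation), the exception being MT-ATP8, which fell 5.34-fold and 4.16-fold. Hypoxia genes rose (median 0.59, 15 of 23, 18 changed when adjusted over the list alone, camera adjusted p = 0.019, and 0.20 with an estimated correlation). Nuclear oxidative phosphorylation genes passed narrowly (median 0.21, 27 of 51 rose and 12 fell, 39 changed when adjusted over the list alone, camera adjusted p = 0.046, and 0.57 with an estimated correlation), and this call was lost with library totals (median -0.03, adjusted p = 0.17), with a mean of at least 1 CPM (0.051), in shAGPG2 alone (0.13) and without shCon replicate 1 (0.059). The lists that did not pass were interferon (median 0.40, camera adjusted p = 0.11), NF-kB (0.91, 0.064), the unfolded protein and integrated stress response (0.17, 0.50), cholesterol synthesis (0.15, 0.68), glycolysis (-0.04, 0.096), leukocyte markers (0.16, 0.55, 2 genes tested) and fibroblast and endothelial markers (0.80, 0.61, 6 genes tested). Without shAGPG1 replicate 2, shAGPG2 replicate 1 or shAGPG2 replicate 2 the NF-kB list passed (adjusted p = 0.045, 0.025 and 0.022), as it did with a mean of at least 1 CPM (0.046). The interferon list passed in shAGPG1 alone (median 0.59, adjusted p = 0.036), and glycolysis with library totals (-0.27, 0.036). Between plvx and shCon the medians were -0.59 for MYC targets, 0.61 for ribosomal proteins, 0.92 for mitochondrially encoded genes and 0.62 for hypoxia. In the shAGPG libraries against plvx, where AGPG itself did not differ, MYC targets were still lower (-0.24, camera adjusted p = 0.00014, and 0.18 with an estimated correlation) and ribosomal proteins higher (0.14, 0.0051, and 0.76 with an estimated correlation). Mitochondrially encoded genes (-0.02, 0.66), nuclear oxidative phosphorylation (0.06, 0.18) and hypoxia (-0.11, 0.20) did not pass there, while NF-kB (-0.60, 3.4e-07, and 0.024 with an estimated correlation) and glycolysis genes (-0.35, 3.4e-07, and 0.060 with an estimated correlation) were lower. Against shCon, where the glycolysis list did not pass, its members SLC16A3 and HK2 were 4.03-fold and 4.11-fold and 3.31-fold and 3.20-fold lower.

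The 2 hairpins against AGPG changed nearly the same genes. Their log2 fold changes correlated across genes (which are not independent replicates) at r = 0.982, with 0.484 in simulations where only sampling noise in the shared shCon libraries linked them. Both-hairpin calls numbered 0.36 on average and 2 at most in those simulations, and 1 gene was called in opposite directions. The simulations do not cover a shared control that itself stands apart. Of 10767 genes changed in both hairpins, 9172 differed in the same direction between plvx and shCon and 86 in the opposite direction. A control that stands apart would itself make the hairpins agree. Directly between hairpins 30 genes differed, 15 each way. A difference beyond 2-fold passed for 2 genes, named here after their values were seen: VAMP7 (log2 difference 3.78, glmTreat adjusted p = 8.7e-05) and ERMARD (-2.24, adjusted p = 0.0019). Without shAGPG1 replicate 2 or shAGPG2 replicate 1 the count of 30 became 91 or 116, and without shAGPG1 replicate 1 it was 18.

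Overexpression of AGPG was set against its vector. In plvx_AGPG 9775 of 14884 genes changed, 4873 up and 4902 down, of which 4873 in all changed at least 2-fold. E2F1 rose 3.68-fold, from 45.1 ± 0.72 CPM in plvx to 166 ± 9.5 in plvx_AGPG (log2 1.88, SE 0.10, edgeR adjusted p = 1.3e-09, n = 2). TRIP6 rose 129-fold from 5.05 ± 0.24 CPM, INSYN1 162-fold and TRPM2 234-fold, and RAB34, with 3 counts in plvx, stood at a ratio of 1110 (counting interval 379 to 5380). Others among the 8 that rose most were INSYN1-AS1, CBLC, PSAT1 and GUCY1A2. EMC10 went from 132 ± 9.4 CPM to no counts, at least 1570-fold lower, SLC6A14 was at least 1050-fold lower, GALC at least 796-fold and SHH at least 369-fold. CACNG4, with 1 count in plvx_AGPG, was lower by a ratio of 11200 (counting interval 2000 to 441000), and UBE2QL1, FOLR1 and BPIFB1 were each at least 362-fold lower. PGR fell by log2 1.32 (SE 0.18), CDK6 12.9-fold, CDKN1A 1.91-fold and CCND1 2.03-fold, while BCL2 rose 3.06-fold and MYC 1.34-fold. ACTG1 fell 1.89-fold and PFKFB3 1.48-fold. Against shCon in the fit of all 16 libraries, BCL2 (log2 -1.84, edgeR adjusted p = 3.1e-14), PGR (2.34, 1e-08), CDKN1A (0.61, 3.2e-06) and ACTG1 (1.22, 1.9e-11) turned in direction, and E2F1 (-0.16, 0.14), CDK6 (0.50, 0.40), CCND1 (-0.20, 0.11), MYC (0.11, 0.28), PFKFB3 (0.13, 0.35), E2F2 (0.09, 0.57) and RB1 (-0.29, 0.087) did not pass. ESR1 fell 1.36-fold (log2 -0.44, SE 0.11, adjusted p = 0.0022) but did not pass when scaled by library totals (log2 -0.24, adjusted p = 0.10, over a range of 1.9e-06 to 0.10 in all alternatives fixed beforehand). CCNE2 (log2 -0.06, SE 0.16, adjusted p = 0.77) and PURA (log2 0.05, SE 0.13, adjusted p = 0.74) did not change. Against shCon in the fit of all 16 libraries PURA was lower (log2 -0.61, edgeR adjusted p = 1.5e-05), and CCNE2 did not pass (-0.31, 0.094). In the E2F and RB family 6 of 13 genes rose and 4 fell, with E2F2 up 2.53-fold and RB1 down 1.95-fold, and in the endocrine panel 8 of 20 rose and 11 fell. Of these calls, E2F5 was lost without plvx replicate 2 (adjusted p = 0.079) or plvx_AGPG replicate 2 (0.057), and NF1 with library totals (0.17) or without plvx replicate 2 (0.083). CDK2 was lost with DESeq2 (0.064) and without plvx replicate 1 (0.11), plvx_AGPG replicate 1 (0.068) or plvx_AGPG replicate 2 (0.14), and PIK3CA with DESeq2 (0.13) and without plvx replicate 1 (0.13) or plvx_AGPG replicate 1 (0.24). E2F8 (log2 -0.32, adjusted p = 0.046) was lost with DESeq2 (0.10), library totals (0.50), no filter (0.079) and the fit of all 16 (0.051), and without plvx replicate 2 (0.057), plvx_AGPG replicate 1 (0.18) or plvx_AGPG replicate 2 (0.25).

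E2F targets rose in plvx_AGPG with a median log2 fold change of 0.50 (46 of 70 rose and 6 fell, 52 changed when adjusted over the list alone, camera adjusted p = 3.3e-05, and 0.37 with an estimated correlation). SLBP rose 3.42-fold, BRCA1 3.08-fold and TK1 3.03-fold. Mitosis genes rose (median 0.37, 34 of 64 and 6 fell, 40 changed when adjusted over the list alone, camera adjusted p = 0.0014, and 0.31 with an estimated correlation), UBE2S by 3.57-fold. MYC targets rose (median 0.46, 19 of 27, 22 changed when adjusted over the list alone, camera adjusted p = 0.0014, and 0.38 with an estimated correlation), TCOF1 by 4.10-fold. Interferon genes rose (median 0.63, 19 of 35 and 7 fell, 27 changed when adjusted over the list alone, camera adjusted p = 0.015, and 0.31 with an estimated correlation), BST2 by 6.52-fold and IFI44 by 25.4-fold. The vector libraries these genes were set against held 17.6% mitochondrial counts, against 8.54% in plvx_AGPG, and had a median of -0.73 for E2F targets and 1.33 for interferon genes relative to shCon. In plvx_AGPG against shCon the E2F list turned to -0.14, and mitosis genes (median 0.05, camera adjusted p = 0.18) and MYC targets (-0.05, 0.39) did not pass.

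Histone genes fell in plvx_AGPG (median -2.08, 30 of 35, 32 changed when adjusted over the list alone, camera adjusted p = 3.1e-07, and 0.31 with an estimated correlation). Some of them again held few counts, such as H3C3 with 39 in plvx and 0 in plvx_AGPG. Basal and mesenchymal genes fell (median -2.10, 13 of 14, 14 changed when adjusted over the list alone, camera adjusted p = 2.1e-06, and 0.31 with an estimated correlation), TGFBI by 74.0-fold. Actin and SRF targets fell (median -0.59, 18 of 25, 22 changed when adjusted over the list alone, camera adjusted p = 2.1e-06, and 0.31 with an estimated correlation), EGR1 by 14.8-fold. Luminal genes fell (median -0.59, 20 of 24, 22 changed when adjusted over the list alone, camera adjusted p = 0.0013, and 0.31 with an estimated correlation), CDH1 by 2.75-fold. NF-kB genes fell (median -1.50, 8 of 10, 9 changed when adjusted over the list alone, camera adjusted p = 0.0015, and 0.31 with an estimated correlation), TNFAIP3 by 14.3-fold. Mitochondrially encoded genes fell (median -1.08, 11 of 13, 12 changed when adjusted over the list alone, camera adjusted p = 0.0014, and 0.58 with an estimated correlation). Estrogen response genes fell (median -0.39, 27 of 47 and 14 rose, 42 changed when adjusted over the list alone, camera adjusted p = 0.015, and 0.31 with an estimated correlation), AREG by 27.3-fold. Targets of p53 fell (median -0.39, 16 of 30, 21 changed when adjusted over the list alone, camera adjusted p = 0.033, and 0.31 with an estimated correlation), GDF15 by 5.97-fold, and this call was lost without plvx_AGPG replicate 1 (adjusted p = 0.058). The plvx libraries stood above shCon in the same lists, by a median of 1.86 for histones and 2.72 for basal and mesenchymal genes. In plvx_AGPG against shCon p53 targets turned to a median of 0.21 (camera adjusted p = 2e-04, and 0.017 with an estimated correlation). Histones (-0.30, 0.096), basal (0.09, 0.40), actin (0.12, 0.50), luminal (-0.08, 0.51), NF-kB (0.61, 0.11), mitochondrially encoded (-0.01, 0.95) and estrogen response genes (-0.04, 0.099) did not pass there. With library totals in place of TMM, neither the estrogen (adjusted p = 0.059) nor the p53 list (0.055) passed. Not called were hypoxia (median -0.39, camera adjusted p = 0.066), ribosomal proteins (-0.29, 0.20), nuclear oxidative phosphorylation (0.16, 0.28), the unfolded protein and integrated stress response (0.18, 0.48), glycolysis (0, 0.75), cholesterol synthesis (-0.06, 0.87), leukocyte markers (0.34, 0.75, 2 genes tested) and fibroblast and endothelial markers (-0.98, 0.43, 5 genes tested). The cholesterol list's mean was 0.05 and the leukocyte list's camera direction was down, opposite in sign to their medians. The hypoxia list passed without plvx replicate 1 (adjusted p = 0.013) and with a mean of at least 1 CPM (0.038), and the ribosomal list passed without plvx replicate 2 (0.032) or plvx_AGPG replicate 2 (0.034).

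**Figure D3:**
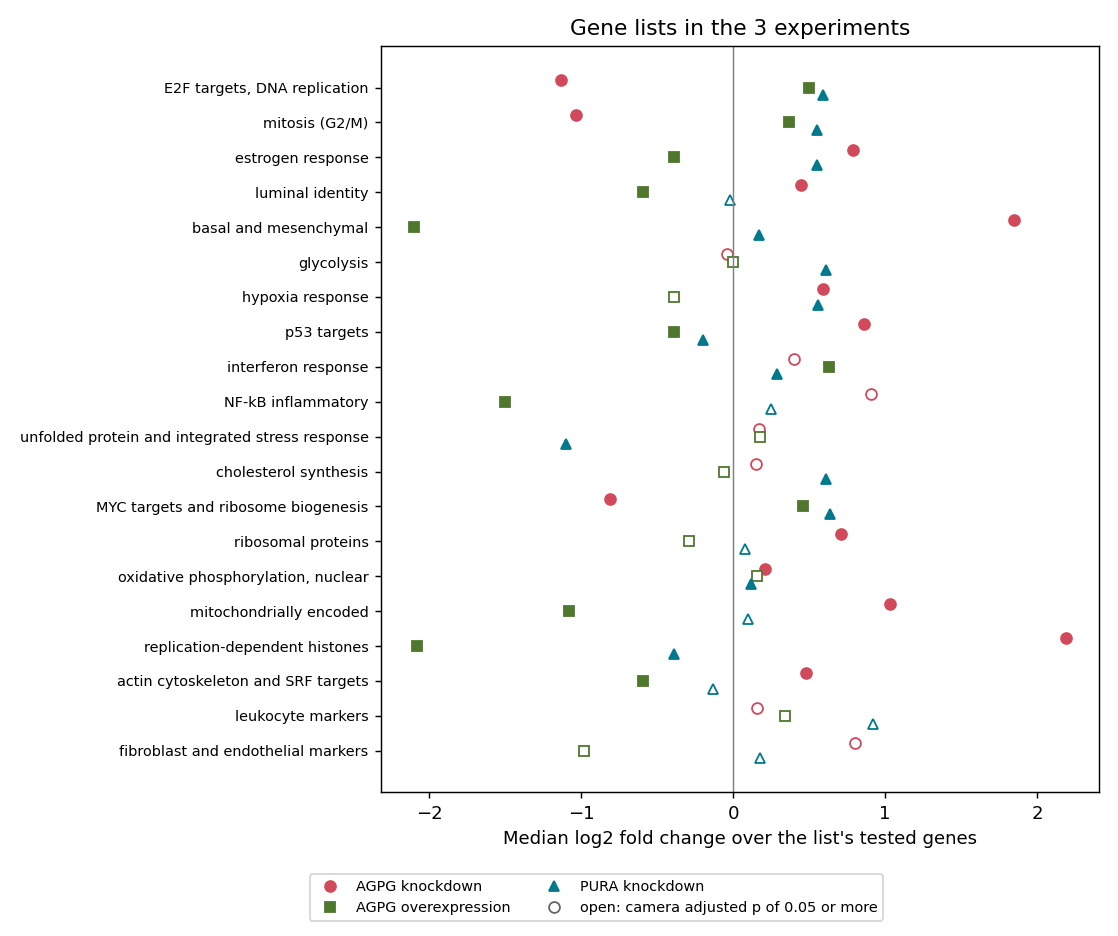
Median log2 fold change of each gene list (x axis) in the AGPG knockdown, AGPG overexpression and PURA knockdown, filled where the camera adjusted p was below 0.05. E2F targets had a median of -1.13, 0.50 and 0.59 in the 3 experiments.

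Knockdown and overexpression of AGPG gave opposite changes across genes. The log2 fold changes of 14594 genes tested in both correlated at r = -0.901 (Spearman -0.849; genes are not independent replicates). Of 8057 genes called in both experiments, 7833 (97.2%) moved in opposite directions, 3975 up in the knockdown and down in the overexpression, where 1714 were expected from the numbers of calls, and 3858 the other way, where 1692 were expected. E2F1, PGR, CDK6, CDKN1A, MYC and BCL2 were among the genes that moved oppositely. The controls of these experiments differed from each other on a similar scale. In the fit of all 16 libraries plvx differed from shCon in 11034 of 16944 genes, 5505 up and 5529 down. E2F1 was 4.15-fold lower in plvx than in shCon (log2 -2.05, SE 0.08, edgeR adjusted p = 6.5e-19), PGR 12.5-fold higher and CDKN1A 2.89-fold higher. The E2F list had a median log2 difference of -0.73 in plvx against shCon (60 of 70 lower, camera adjusted p = 2.9e-10, and 0.0051 with an estimated correlation). Of the 10767 genes changed in both AGPG hairpins, 9172 differed in the same direction between plvx and shCon and 86 in the opposite direction. The root mean square log2 distance was 1.51 between shCon and shAGPG1 and 1.45 between shCon and plvx, but 0.576 and 0.574 between plvx and the shAGPG groups and 0.644 between shCon and plvx_AGPG.

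Comparing the treated libraries with the other experiment's control gave fewer genes. The shAGPG libraries differed from plvx in 4775 genes, 607 of them at least 2-fold, and plvx_AGPG differed from shCon in 4256, 820 at least 2-fold. E2F1 was 1.22-fold lower in the shAGPG libraries than in plvx (log2 -0.29, SE 0.07, edgeR adjusted p = 0.0039), and CDKN1A 2.06-fold and PGR 4.93-fold higher. AGPG itself did not differ there (log2 -0.12, SE 0.37, edgeR adjusted p = 0.86). In plvx_AGPG against shCon, E2F1 did not differ (log2 -0.16, SE 0.08, adjusted p = 0.14), and the E2F list had a median of -0.14 (16 of 70 lower and 1 higher, camera adjusted p = 0.00023, and 0.058 with an estimated correlation). Interferon genes were higher in plvx_AGPG than in shCon (median 1.57, 31 of 35, camera adjusted p = 3.3e-94, and 5.1e-06 with an estimated correlation) and lower in the shAGPG libraries than in plvx (median -1.10, 30 of 35, camera adjusted p = 2.8e-33, and 1e-04 with an estimated correlation). The vector plvx alone also stood above shCon for this list (median 1.33, 26 of 35 higher, camera adjusted p = 1.2e-07, and 0.013 with an estimated correlation). Both of these comparisons therefore carry a difference between the control sets.

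Neighbouring genes moved together in both AGPG experiments. In the knockdown 46 of 291 windows of 50 consecutive genes lay more than 0.5 (log2) from the median of all genes, 19 higher and 27 lower, where permuted gene positions gave 2.3 on average and 7 at most. In the overexpression 47 of 284 windows did, and the window medians of the 2 experiments correlated at r = -0.905. On chromosome 18, 35972083 to 57586772 (GRCh38), the median was -1.56 in the knockdown and 1.30 in the overexpression. On chromosome 6, 24402908 to 27139881, which holds many histone genes, it was 1.37 and -1.61. In the PURA knockdown 0 of 306 windows passed, and permutations also gave 0.

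**Figure D4:**
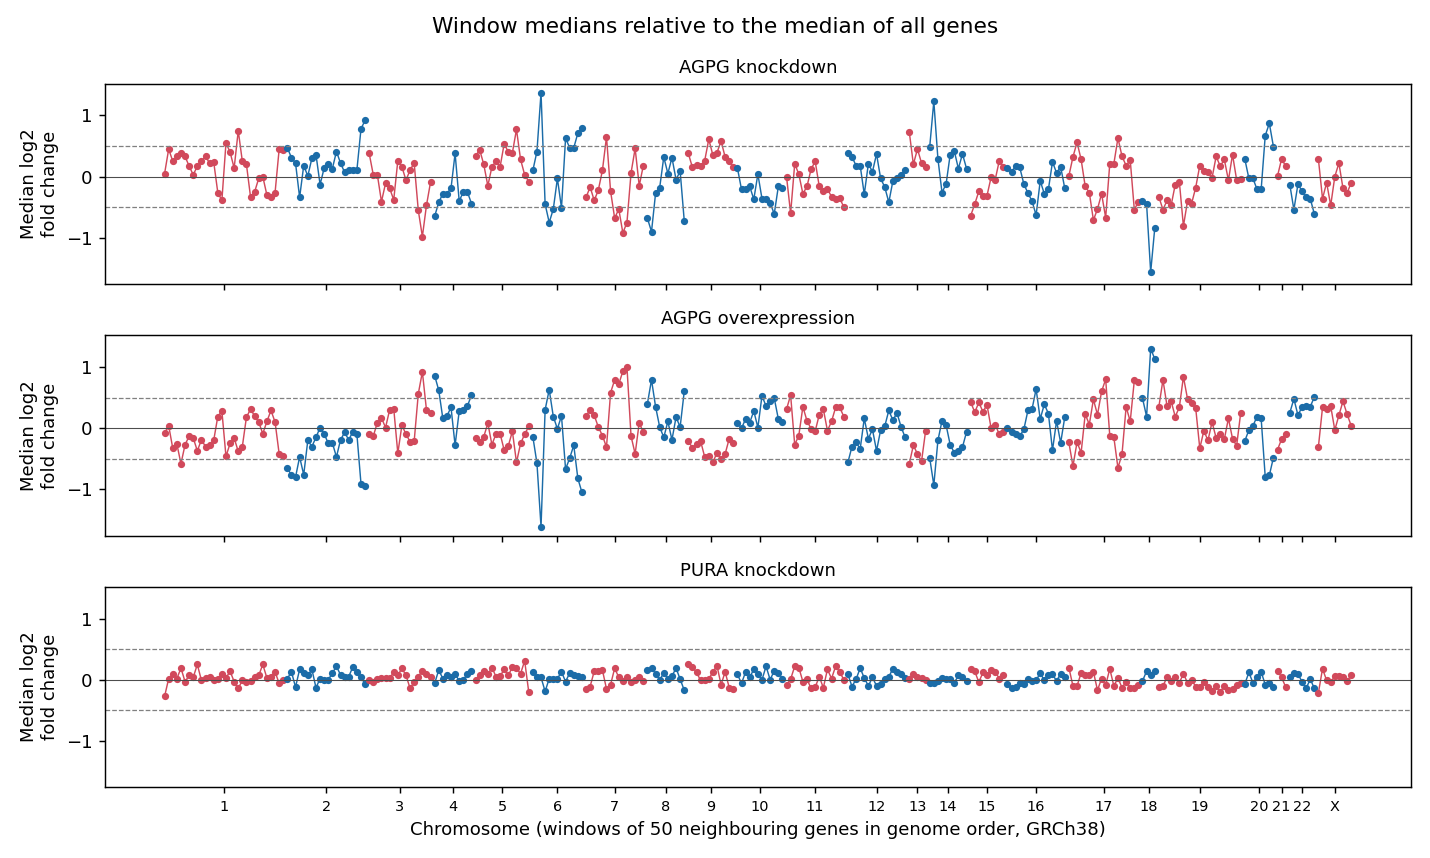
Median log2 fold change of windows of 50 neighbouring genes, relative to the median of all genes, in genome order for the 3 experiments, with dashed lines at 0.5 on either side of 0 and colors alternating by chromosome. Windows in the AGPG knockdown and overexpression mirror each other, and those of the PURA knockdown stay inside the dashed lines.

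Knockdown of PURA asks whether this protein acts on the same genes as AGPG. In both hairpins 5827 of 16024 genes changed in the same direction, 2889 up and 2938 down, and 1042 of them at least 2-fold in each. By hairpin, 7682 genes changed in shPURA1 (3844 up, 3838 down) and 7078 in shPURA2 (3522 up, 3556 down). Stress response genes were among those that fell most. DDIT3, which encodes the transcription factor CHOP, fell 8.57-fold and 7.77-fold from 145 ± 4.0 CPM (log2 -3.10 and -2.96, SE 0.09, edgeR adjusted p = 3.5e-15 and 7.2e-15, n = 2). The chaperone gene HSPA5 fell 4.76-fold and 5.28-fold from 3100 ± 13 CPM, CHAC1 8.93-fold and 6.73-fold and NUPR1 5.31-fold and 5.74-fold, with SLC22A31, RASD1, KRT86 and SLC43A1 also among the 8 that fell most. PTGS1 rose 8.16-fold and 6.70-fold, TRGC1 6.46-fold and 8.33-fold and the chemokine gene CXCL12 5.95-fold and 9.33-fold, followed by GALNT18, PADI3, IFIT1, LOXL2 and RIMKLA.

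Proliferation genes rose in the PURA knockdown relative to shCon_PURA. E2F targets had a median log2 fold change of 0.59 in the mean of both hairpins, with 61 of 70 up and 1 down, 63 changed when adjusted over the list alone (camera adjusted p = 9.6e-24, and 0.018 with an estimated correlation). MCM10 rose 3.71-fold and 2.61-fold, CDC25A 3.30-fold and 2.60-fold and UHRF1 3.61-fold and 2.30-fold. E2F1 rose 1.43-fold in shPURA1 (log2 0.52, SE 0.08, edgeR adjusted p = 2.3e-05) and 1.18-fold in shPURA2 (log2 0.24, SE 0.08, adjusted p = 0.020). The call in shPURA2 was lost with library totals (adjusted p = 0.085), with DESeq2 (0.051) and without shCon_PURA replicate 1 (0.062), shCon_PURA replicate 2 (0.082) or shPURA2 replicate 1 (0.054), over a range of 0.012 to 0.085. Mitosis genes rose (median 0.55, 53 of 65, 58 changed when adjusted over the list alone, camera adjusted p = 6.3e-17, and 0.019 with an estimated correlation), MKI67 by 2.22-fold and 1.83-fold. MYC targets rose (median 0.64, 23 of 27, 25 changed when adjusted over the list alone, camera adjusted p = 2.1e-16, and 0.018 with an estimated correlation), HSPD1 by 2.33-fold and 2.28-fold. In the E2F and RB family 7 of 13 genes rose and 2 fell in both hairpins, RBL1 rising 2.27-fold and 2.03-fold and RBL2 falling 2.45-fold and 2.27-fold. The control itself stood apart in the fit of all 16 libraries, with a median for E2F targets in shCon_PURA of -1.36 against shCon (66 of 70 lower, camera adjusted p = 7e-32, and 0.00014 with an estimated correlation) and -0.65 against plvx. In the shPURA libraries against shCon the direction turned for E2F targets (-0.66, camera adjusted p = 5.7e-18), MYC targets (-1.04, 1.3e-15), E2F1 (log2 -1.58 and -1.86), RBL1 (-0.49) and RBL2 (0.65), and mitosis genes did not pass (-0.12, 0.14). CCNE2 rose 1.71-fold in shPURA1 (log2 0.78, SE 0.14, edgeR adjusted p = 0.00013) but did not pass in shPURA2 (log2 0.33, adjusted p = 0.072), where it passed without shCon_PURA replicate 1 (0.019) or shPURA2 replicate 2 (0.018), and against shCon it turned (-0.79 and -1.24).

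Among the other genes followed in every comparison, ACTG1 and CCND1 differed between the hairpins against PURA. ACTG1 fell in shPURA2 (log2 -0.53, SE 0.09, edgeR adjusted p = 6.9e-05) and did not pass in shPURA1 (log2 -0.12, adjusted p = 0.26), with a difference of 0.40 between hairpins (adjusted p = 0.011). CCND1 fell in shPURA2 (log2 -0.47, adjusted p = 6.6e-05) and did not pass in shPURA1 (0.02, adjusted p = 0.85), with a difference of 0.49 (adjusted p = 0.00081). Against shCon ACTG1 turned to 0.58 and 0.17, and CCND1 in shPURA1 to -0.53. MYC and CDK6 did not differ between hairpins (log2 -0.09, adjusted p = 0.61, and 0.72, adjusted p = 0.21). MYC fell in shPURA1 (log2 -0.24, SE 0.07, adjusted p = 0.012), a call lost without shCon_PURA replicate 2 (0.16) or shPURA1 replicate 1 (0.11), and in shPURA2 (log2 -0.15, adjusted p = 0.11) it passed only with library totals (-0.19, adjusted p = 0.047). CDK6, at 1.07 ± 0.085 CPM in shCon_PURA, rose in shPURA1 (log2 0.82, SE 0.29, adjusted p = 0.027) and did not pass in shPURA2 (log2 0.10, adjusted p = 0.83). The CDK6 call was lost with DESeq2 (0.17) and without shCon_PURA replicate 1 (0.12), shCon_PURA replicate 2 (0.060), shPURA1 replicate 1 (0.068) or shPURA1 replicate 2 (0.12). In the endocrine panel 3 of 19 tested genes rose and 4 fell in both hairpins.

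The list of the unfolded protein and integrated stress response was lower in the PURA knockdown than in shCon_PURA (median -1.10, 25 of 27 down and 2 up, 27 changed when adjusted over the list alone, camera adjusted p = 7e-48, and 0.018 with an estimated correlation). Targets of p53 fell (median -0.20, 15 of 30, 18 changed when adjusted over the list alone, camera adjusted p = 2.1e-06, and 0.028 with an estimated correlation), with CDKN1A 1.63-fold and 1.49-fold and BBC3 2.74-fold and 2.95-fold lower. Cholesterol synthesis genes rose (median 0.61, 18 of 23, 21 changed when adjusted over the list alone, camera adjusted p = 4.5e-14, and 0.023 with an estimated correlation), HMGCS1 by 3.05-fold and 2.28-fold. Glycolysis genes rose (median 0.61, 14 of 20, 15 changed when adjusted over the list alone, camera adjusted p = 3.2e-09, and 0.023 with an estimated correlation), LDHA by 1.82-fold and 2.02-fold and PFKFB3 by 1.71-fold and 1.73-fold. Estrogen response genes rose (median 0.55, 28 of 43, 35 changed when adjusted over the list alone, camera adjusted p = 3e-09, and 0.024 with an estimated correlation), GREB1 by 3.18-fold and 3.79-fold, and ESR1 itself rose 1.32-fold and 1.68-fold from 42.2 ± 3.0 CPM. Hypoxia genes rose (median 0.56, 16 of 25 and 6 fell, 22 changed when adjusted over the list alone, camera adjusted p = 4e-05, and 0.039 with an estimated correlation), ANGPTL4 by 2.38-fold and 2.40-fold. The control was high for the stress response list, with a median in shCon_PURA of 1.36 above shCon (26 of 27 higher, camera adjusted p = 8e-20, and 0.0017 with an estimated correlation) and 1.34 above plvx (0.0097 with an estimated correlation), and low for estrogen response (-1.44 against shCon, 0.00043 with an estimated correlation). Against shCon the shPURA libraries turned in direction for the stress response (0.39, camera adjusted p = 0.0047), p53 targets (0.37, 0.0096), estrogen response (-0.78, 6e-12), ESR1 (log2 -1.67 and -1.33) and CDKN1A (1.70 and 1.83), while cholesterol synthesis (0.54, 1.8e-07), hypoxia (1.91, 1.4e-27) and glycolysis genes (0.27, 0.00056) stayed higher. With an estimated correlation neither the stress response (adjusted p = 0.14) nor the glycolysis list (0.16) passed in that comparison. For hypoxia shCon_PURA itself stood above shCon (median 1.6, 23 of 25 higher, camera adjusted p = 4.6e-12, and 0.017 with an estimated correlation). The 1.91 of the hypoxia list thus includes a difference between controls. The control medians were 0.03 for cholesterol synthesis and -0.17 for glycolysis.

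Smaller list changes after PURA knockdown were those of replication-dependent histones, which fell (median -0.39, 15 of 29, 15 changed when adjusted over the list alone, camera adjusted p = 0.014, and 0.31 with an estimated correlation), and of interferon genes, which rose (median 0.29, 16 of 35 and 6 fell, 23 changed when adjusted over the list alone, camera adjusted p = 0.027, and 0.20 with an estimated correlation). The interferon call did not pass in shPURA1 alone (adjusted p = 0.19) and was lost without shCon_PURA replicate 1 (adjusted p = 0.055), though IFIT1 rose 4.37-fold and 6.44-fold. Nuclear oxidative phosphorylation genes rose (median 0.12, 21 of 51, 24 changed when adjusted over the list alone, camera adjusted p = 0.023, and 0.69 with an estimated correlation), a call lost without shCon_PURA replicate 1 (adjusted p = 0.20) or shPURA2 replicate 2 (0.056). Basal and mesenchymal genes rose (median 0.17, 5 of 13, 6 changed when adjusted over the list alone, camera adjusted p = 0.034, and 0.19 with an estimated correlation), LOXL2 by 4.78-fold and 4.32-fold, though the list did not pass in shPURA1 alone (adjusted p = 0.054). Against shCon, histones (0.17, camera adjusted p = 0.43) turned and oxidative phosphorylation (0.23, 0.081) did not pass. Not called were luminal identity (median -0.02, camera adjusted p = 0.44), NF-kB (0.25, 0.33), ribosomal proteins (0.08, 0.11), mitochondrially encoded genes (0.10, 0.39), actin and SRF targets (-0.13, 0.63), leukocyte markers (0.92, 0.094, 2 genes tested) and fibroblast and endothelial markers (0.18, 0.48, 4 genes tested). The mean of the actin list was 0.04 and the camera direction of the fibroblast list was down, opposite in sign to their medians. Ribosomal and mitochondrially encoded genes passed without shCon_PURA replicate 2 (adjusted p = 8.9e-05 and 0.00043), and ribosomal genes also without shPURA2 replicate 1 (0.011). Mitochondrially encoded genes also passed in shPURA2 alone (0.045).

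The hairpins against PURA gave similar changes at unequal PURA levels. Their log2 fold changes correlated across genes at r = 0.886, with 0.499 in simulations where only sampling noise in shared controls linked them, and 35 genes were called in opposite directions. Between the hairpins 533 genes differed, 357 higher in shPURA1 and 176 higher in shPURA2. Of these, 2 passed for a difference beyond 2-fold, named after their values were seen: PITHD1 (log2 difference 1.55, glmTreat adjusted p = 0.017) and FGFRL1 (-1.40, adjusted p = 0.022). The count of 533 became 132 without shPURA1 replicate 1, 107 without shPURA1 replicate 2, 971 without shPURA2 replicate 1, 893 without shCon_PURA replicate 1 and 887 without shCon_PURA replicate 2.

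The knockdowns of AGPG and PURA were compared directly. Across 14416 genes their log2 fold changes correlated at r = -0.208 (Spearman -0.227), and 2777 of 4124 genes called in both (67.3%) moved in opposite directions. Of these, 1256 were up with AGPG knockdown and down with PURA knockdown, where 878.9 were expected, and 1521 the other way, where 1033 were expected. For the AGPG overexpression and the PURA knockdown r was 0.169 (Spearman 0.158). E2F targets differed between the knockdowns, with a median difference of log2 fold changes of -1.79 and all 70 genes lower in the AGPG knockdown (camera adjusted p = 3e-33, and 0.00012 with an estimated correlation). This includes the difference between the controls, whose median for the list was -1.36 in shCon_PURA against shCon (66 of 70 lower). Against shCon both sets of treated libraries were lower, with medians of -1.13 (shAGPG) and -0.66 (shPURA, 62 of 70 lower). Control libraries differed here as well: shCon_PURA was apart from shCon in 11483 of 16944 genes, with E2F1 4.29-fold lower (log2 -2.10, SE 0.08, edgeR adjusted p = 4.6e-19), ESR1 4.22-fold lower and PGR without a count. PGR was too low to be tested within the PURA experiment.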

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

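All 12 differences between hairpins came from a planned test of the difference. The tests of a swap of the shCon and plvx labels, and of plvx and plvx_AGPG, were chosen only after the result was seen, and the prediction for GC content and length was written after the 46 windows below but before its own result.

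The shAGPG1 and shAGPG2 effects differed by camera in 6 lists, given as the median log2 difference of shAGPG1 minus shAGPG2. These were interferon (0.29, camera adjusted p = 8e-15), ribosomal proteins (0.19, 1.8e-38), nuclear oxidative phosphorylation (0.12, 1.6e-14), MYC targets (0.06, 0.036), hypoxia (-0.06, 0.0079) and mitochondrially encoded genes (-0.19, 1e-10). None passed with an estimated correlation, where the adjusted p ran from 0.29 to 0.57. The shPURA1 and shPURA2 effects differed in 6 lists, E2F targets (0.25, camera adjusted p = 1.1e-27), cholesterol synthesis (0.20, 2.8e-08), mitosis (0.12, 9e-05), MYC targets (0.12, 0.0015), interferon (-0.15, 2.4e-05) and mitochondrially encoded genes (-0.38, 2.8e-08). Only the E2F difference passed with an estimated correlation (adjusted p = 0.042), and the others ran from 0.12 to 0.42. None of the genes named by the rule fixed beforehand passed for a difference beyond 2-fold between the hairpins of a pair.

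The first pattern weighed was that the shAGPG and plvx libraries stood apart from the shCon and plvx_AGPG libraries. Cells of 2 sub-lines with different copy number remain a candidate explanation: 46 windows of neighbouring genes lay past 0.5 in the AGPG knockdown, though no DNA was measured and 46 remained after a trend on GC content and length was taken out, which excluded that bias as the whole cause. A graded response to the AGPG level was not seen between shCon and plvx_AGPG, at 17.3-fold more AGPG. Genes changed in both hairpins moved there by a median of -0.05 when oriented by the sign of shCon minus knockdown. These groups belong to different experiments, so a difference between their cells or a swap of control labels could mask such a response. A response that levels off by the shCon amount would also give little change here, so a graded response stays open. Scaling by mitochondrial transcripts was tested by leaving them out, and 0.996 of the count of changed genes stayed. TMM already limits the pull of such abundant genes, so this speaks only to the TMM-scaled calls. Leaving them out under library totals alone was not tried. A swap of plvx and plvx_AGPG was excluded by a ratio of 60.6 between the lowest plvx_AGPG and the highest plvx AGPG level, as a share of library totals without TMM. A swap of the shCon and plvx labels could not be told apart, with AGPG in the hairpin libraries at log2 -0.12 (SE 0.37) from plvx.

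The other pattern was that the shPURA libraries differed from shCon_PURA in 5827 genes while PURA fell little. With 0 windows of 50 genes past 0.5, no copy number difference large enough to move a window that far was seen. Smaller differences could not be excluded by this threshold. The window medians had an SD of 0.11, against 0.083 with permuted gene positions. A response in proportion to PURA mRNA could not be decided by the planned ratio. Over the 5827 genes changed in both hairpins, the median ratio of the shPURA2 to the shPURA1 change was 0.96. The ratio for PURA itself was 0.30 (SE 0.20). The value of 0.96 lay past the margin of 0.3 written beforehand, also with 1 SE added to it after the value was seen, but not with 2 SE. However, genes that changed little in shPURA2 tended to miss the call and be left out. Both changes also share the shCon_PURA libraries, which draws the ratio toward equality. Without that selection, 7682 genes changed in shPURA1 and 7078 in shPURA2. PURA protein was not measured, so a graded response to the protein stays untested.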

How the results depend on the processing

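Of 617 single-gene results, 6996 of 7141 values under alternatives fixed beforehand kept their direction and side of the threshold, 120 fell below it, 24 passed it and 1 reversed (NF1 in shAGPG1, -0.04 with library totals). Of 60 list results, 632 of 700 such values kept both, 42 fell below and 26 passed, with 0 reversed. With the alternatives added later, these were 7019 of 7199 (127 below, 26 past, 27 reversed) and 658 of 760 (50, 30 and 22). The cause was not tested unless stated.

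Asking for a log2 fold change of at least 1 left, by construction, 5654 genes in shAGPG1, 5646 in shAGPG2, 5168 in both, 4873 in plvx_AGPG, 1587 in shPURA1, 1396 in shPURA2 and 1042 in both, with 7 between the AGPG and 33 between the PURA hairpins. The 30 genes between AGPG hairpins became 9 with DESeq2, 102 without a filter and 3 in the fit of all 16. The 533 between PURA hairpins became 801 without a filter and 802 with the replicate number as a block. Leaving out 1 library, where a lone sample is assumed to vary like the other groups, gave 10801 to 11645 genes for shAGPG1, 10594 to 11730 for shAGPG2, 10116 to 10343 for both, 8662 to 9535 for plvx_AGPG, 5596 to 8224 for shPURA1, 6025 to 6641 for shPURA2 and 4494 to 5484 for both. Between hairpins it gave 18 to 116 (AGPG) and 107 to 971 (PURA). The correlation of the AGPG and PURA knockdowns was -0.239 and -0.251 with a mean of at least 1 and 10 CPM, -0.195 for shAGPG2 with shPURA2, and -0.208 to -0.18 without 1 library. That of the AGPG knockdown and overexpression was -0.899 to -0.884.

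With an estimated correlation, camera called 2 lists in the AGPG knockdown and 0 in the overexpression, where the E2F list (median 0.5) lost its call (adjusted p = 0.37). With fry 20 were called in the AGPG knockdown. There the estimated correlations of the E2F (-0.0036), p53 (-0.021) and estrogen lists (-0.0066) lay below the preset 0.01. Those of the luminal (0.06) and basal lists (0.046) lay above it. For the lists below it, the higher p-values did not come from a higher correlation. Other control libraries were tallied only for the lists and the 12 genes followed in every comparison, so the reversals below are those of these genes. With plvx as control, 3998, 3803 and 2972 genes changed in shAGPG1, shAGPG2 and both. The lists that reversed were basal (-0.55), hypoxia (-0.11), interferon (-1.1), NF-kB (-0.6) and actin (-0.42). Lists called against shCon that no longer passed were estrogen (0.08), luminal (0.08), histones (-0.04), mitochondrial (-0.02) and oxidative phosphorylation (0.06), the direction of camera staying up in all 5. Of the 12 genes, those reversed were AGPG (0.25 in shAGPG2), PURA (0.33, 0.51), PFKFB3 (-0.06 in shAGPG2), ACTG1 (-0.52, -0.49) and CCND1 (-0.28, -0.28). With shCon as control, 4256 genes and 6 lists changed in plvx_AGPG. The lists newly called included nuclear oxidative phosphorylation (0.33) and the stress response (0.32). With an estimated correlation E2F targets (adjusted p = 0.058), the stress response (0.1), ribosomal proteins (0.45) and oxidative phosphorylation (0.32) did not pass. Interferon (5.1e-06) and p53 targets (0.017) did. Lists were counted as reversed by the direction of camera. These were E2F (-0.14), basal (0.09), p53 (0.21), NF-kB (0.61), MYC (-0.05), ribosomal (0.37) and actin (0.12), and also estrogen (-0.04), luminal (-0.08) and mitochondrial (-0.01), whose medians shrank and kept their sign. Of the 12 genes, PURA (-0.61), E2F1 (-0.16), PFKFB3 (0.13), ACTG1 (1.22), CDK6 (0.5), CDKN1A (0.61) and PGR (2.34) reversed. With shCon as control in the PURA knockdown, reversed lists were E2F (-0.66), mitosis (-0.12), estrogen (-0.78), p53 (0.37), stress response (0.39), MYC (-1.04) and histones (0.17). Of the 12 genes, E2F1 (-1.58, -1.86), ESR1 (-1.67, -1.33), ACTG1 (0.58, 0.17), CCND1 (-0.53 in shPURA1), CCNE2 (-0.79, -1.24) and CDKN1A (1.7, 1.83) reversed. Among reported panel genes outside the 12, BCL2 turned in the AGPG knockdown (0.26) and overexpression (-1.84), CDK2 (-0.20) and PIK3CA (-0.07) in the overexpression, and RBL1 (-0.49) and RBL2 (0.65) in the PURA knockdown.

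Replicate numbers share only a number here, with correlations from -0.138 to 0.149, and the crossed block gave 10702 genes in the overexpression. Controls of 2 libraries could not be split. At these depths AGPG held 4 to 40 counts per library in the AGPG knockdown, so its fold change there is limited by counting error.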
